A study of Homo sapiens with 10 samples.

How the data were processed

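The series holds 10 samples of fresh frozen uterine leiomyoma tissue from 5 donors, 5 PGR ChIP libraries and 5 chromatin inputs. Per the labels' protocols, chromatin was immunoprecipitated with an antibody to PGR and sequenced from adapter-ligated libraries. The submitters' processing notes name cutadapt, Bowtie2 and HOMER and the hg19 build, and their versions are not given in the sources used here. Per the file headers of libraries 1, 3 and 5, HOMER's findPeaks called peaks in each library separately against its own input, in the style for transcription factors. A peak had to reach 4 times the input and 4 times the local region of 10 kb, each with a Poisson p of at most 1e-04, at a false discovery rate of 0.001. The lists of libraries 2 and 4 are annotation tables made from peaks and give no call settings, and those settings are not given in the sources used here.

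Each deposited list gives a position and a signal per peak, the tag count scaled to 10000000 tags, per the file headers. In libraries 2 and 4 the deposited peak score was read as the same quantity, because its values are whole multiples of a fixed step and their sum has the same scale. The lists of libraries 1, 3 and 5 also give the authors' ratio of the peak to its input, called fold over input here, and the input tags themselves. The annotation of libraries 2 and 4 (gene of the nearest TSS, feature class, distance to the TSS, repeat) is the authors' own. It was transferred to a merged region from whichever of these lists had the higher-ranked peak there. Both lists named the same gene in 99.2% of the regions of all 5 libraries.

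Peaks on the Y chromosome were left out, which leaves 189884. Regions are unions of peaks that overlap by at least 1 bp. The same 88311 regions came from bedtools 2.31.1. Peak widths are fixed per library at 216, 90, 162, 170 and 160 bp in libraries 1 to 5. Heights of different lists were never compared directly. They were used as ranks within a list or as ratios within a library. The step of the heights was taken as the spacing that put most heights under 10 on whole multiples within 0.005. Only a set range of spacings around those of the known depths was searched, so a far lower depth could not be returned. It was found for all such heights of libraries 2, 4 and 5, and for library 5 it returned 100.0% of the depth in its header.

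Random placement put every peak at a uniform position between the outermost peaks seen on its chromosome, 100 times. For the gene lists, Entrez gene identifiers of the authors' annotation were joined to a table of GRCh38.p14 gene names, of which no coordinate was used. Of 12252 annotated identifiers, 12206 were found. All 478 entries of the 21 lists matched, 476 by symbol and 2 by a synonym. A member counted when it was the nearest gene of a region of all 5 libraries, and the count was set against 10000 random lists of protein-coding genes. Matching on gene length and on neighbouring genes was planned, and no hg19 annotation was used here, so the planned unmatched test became the main one. Benjamini-Hochberg adjustment covered the 21 lists. These p-values describe the shared set and do not measure spread between donors. Differences over libraries were tested by exact sign-flip permutation, two-sided. Intervals of shares are Wilson 95% intervals and cover counting error only.

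Genes to name were fixed before the data were examined. They are the 20 regions of all 5 libraries with the best mean percentile of height, at most 1 per nearest gene, then up to 4 members of each list with the best-ranked region within 20 kb of the TSS, and 10 genes whatever their result. Regions on chromosomes 8 and Y, the mitochondrial genome and unplaced sequence were left out of naming, and some genes that the rule names are not reported here. The alternatives fixed at the same time were an overlap of at least 50% of the shorter peak, the upper 50% of each list by height, lists of equal length, leaving out each library, regions of at least 3 libraries, a promoter window of 1 kb on both sides, distances of 5 and 100 kb for gene lists, and the mean of log2 fold. Shares of DNA motifs, 20 patterns fixed beforehand, need genome sequence and were not analysed here. The code was tested on simulated data. For the merging of peaks, 2000 of 2000 planted shared regions were recovered with 0 other peaks called shared. In that simulation planted shared peaks always overlapped and other peaks never could. It therefore checks the code only, and not how merging behaves where peaks are dense. For the list test, 100 of 100 simulated lists with 12 of 25 members near regions passed, and 1 of 400 random lists did. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.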

Results

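Binding of the progesterone receptor (PGR), a hormone-activated transcription factor, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in uterine leiomyoma, a benign tumour of the smooth muscle of the uterus that grows in response to progesterone. Fresh frozen tissue of 5 donors gave 5 PGR libraries, called library 1 to library 5 here, and each had its own chromatin input library and its own list of binding peaks. Outside the Y chromosome, the lists held 63097, 12015, 38846, 31471 and 44455 peaks in libraries 1 to 5. The sequencing depth was 48444951, 46373328 and 36107655 tags in libraries 1, 3 and 5. The depths of libraries 2 and 4, recovered from the spacing of their peak heights, were 95.5% and 91.4% of that of library 5. The share of all tags that fell in peaks was 10.7%, 0.713%, 3.16%, 3.29% and 4.69% in libraries 1 to 5. Peak height is the authors' tag count scaled to 10000000 tags per library, and coordinates are those of the hg19 build.

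The first question was which parts of the genome PGR occupied in every tumour. The peaks merged into 88311 regions, and 7448 of them held a peak of all 5 libraries. Among the strongest of these were regions at FKBP5, a co-chaperone of steroid receptors, at ZBTB16, a zinc finger repressor, at NFKBIA, the inhibitor of NF-kappa-B, at the clock gene PER1, and at DDIT4, an inhibitor of mTORC1. All are textbook targets of progesterone or glucocorticoid receptors, which recognise the same DNA element. Regions were ranked by the mean, over the 5 libraries, of the height percentile within each library's list.

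The highest-ranked region lay on chromosome 9 at 93805400 to 93805621, in intergenic sequence 31.9 kb downstream of the start of the non-coding gene LOC100129316, with folds over input from 80.2 to 169 in the 3 libraries whose lists give that value (1, 3 and 5). Ranks 2 and 3 both fell in intron 3 of 6 of ZBTB16 on chromosome 11, at 114050041 to 114050319 and at 114033614 to 114033830. For the former, the nearest transcription start site (TSS) was that of NNMT, the nicotinamide N-methyltransferase gene, 116 kb away. Fold over input was 45.9 to 112 and 80.2 to 179 at these regions. ADARB1, an RNA-editing enzyme gene, had a rank 4 region in intron 1 of 11 on chromosome 21 at 46540989 to 46541205, with 168 to 176 times the input. A region at NFKBIA on chromosome 14, at 35873066 to 35873306 in intron 1 of 5 and 739 bp from the TSS, ranked 9, with a mean height percentile of 99.9 ± 0.107 (SD, n = 5) and 85.0 to 267 times the input. DDIT4 had its region 18.6 kb upstream of the TSS on chromosome 10 at 74014913 to 74015129, where fold over input was 54.6 to 79.8. HIF3A, a hypoxia-inducible factor subunit, had one 2.54 kb from its TSS in intron 1 of 11 on chromosome 19 at 46804217 to 46804433, with 56.4 to 737 times the input. PER1 had a region 2.05 kb upstream of its TSS on chromosome 17 at 8057689 to 8057905, with 41.1 to 115 times the input. The other regions named by rank were nearest to ARHGEF18, LOC101928731, PRDM11, LOC101928617, MIR5690, TPRG1-AS1, LINC01088, MIR7706, CD180, PIK3C2G and LAMA3, besides FKBP5. LAMA3, a laminin chain gene, held its region inside intron 21 of 73 on chromosome 18 at 21406112 to 21406351. Only TPRG1-AS1, whose region lay 500 bp from the TSS on chromosome 3, had a region of the authors' promoter class among these 20. That class leaves out some regions near a TSS. Those at NFKBIA and FKBP5, 739 and 439 bp downstream of the TSS, were classed as intron.

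FKBP5 had regions of all 5 libraries around its TSS and inside the gene. The strongest region lay 439 bp from the annotated TSS on chromosome 6 at 35695823 to 35696043 and ranked 11, with a mean percentile of 99.9 ± 0.193 (SD, n = 5) and a fold over input of 96.9 to 172. Another lay 3.44 kb upstream at 35699690 to 35699920, with a mean percentile of 99.2 ± 0.797 (SD, n = 5). A region inside intron 6 of 11 of FKBP5, at 35569754 to 35569987, was assigned to the microRNA gene MIR5690 by its nearest TSS and ranked 13. The window drawn around FKBP5 held 13 regions with a peak in more than 1 library, of which 4 had all 5 libraries and 4 had 4.

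**Figure D1:**
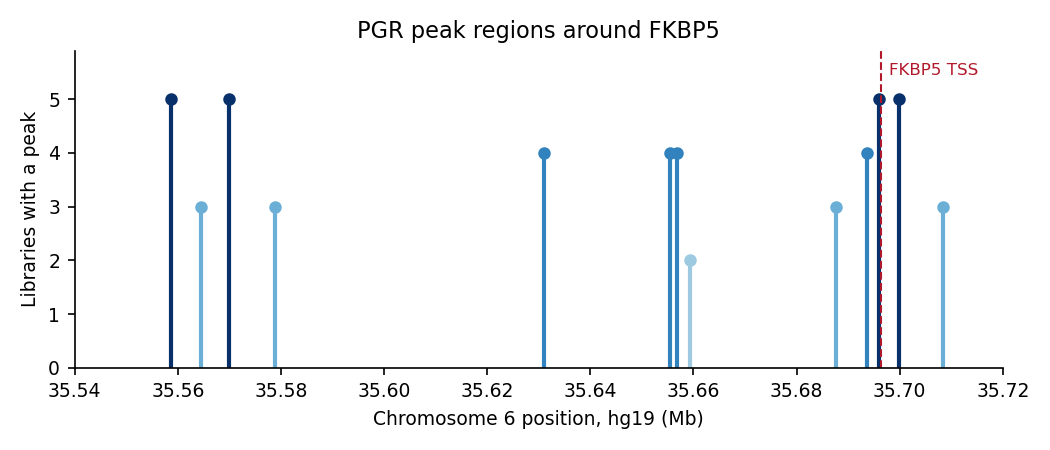
Map of PGR peak regions on chromosome 6 around FKBP5, with hg19 position in Mb on the horizontal axis and the number of libraries with a peak on the vertical axis; each stem is a region found in more than 1 library and the dashed line is the annotated TSS of FKBP5. Of the 13 regions, 4 have a peak in all 5 libraries, and the region at 35695823 to 35696043 lies 439 bp from the TSS.

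Genes chosen in advance for their place in leiomyoma biology differed in PGR occupancy. PGR itself was the nearest gene of 3 regions of all 5 libraries on chromosome 11, at 100949193 to 100949437 in intron 2 of 6, and upstream at 101059736 to 101059959 and 101068492 to 101068708, 59.3 and 68.0 kb from the TSS. Mean height percentiles were 94.0 ± 4.69, 79.1 ± 35.6 and 96.5 ± 3.82 (SD, n = 5). ESR1, the oestrogen receptor alpha gene, had 2 such regions on chromosome 6. One was in its intron 2 of 9 at 152039682 to 152039933, and the other in the neighbouring gene CCDC170 at 151937359 to 151937575, 74.2 kb upstream. TDO2, the enzyme that opens the tryptophan ring, had 1 region in intron 8 of 11 on chromosome 4 at 156836067 to 156836291, 11.3 kb from the TSS, with a mean percentile of 94.1 ± 4.23 (SD, n = 5) and 20.5 to 142 times the input. BCL2, a suppressor of apoptosis, had 3, between 157 and 264 kb from its TSS. The smooth muscle actin gene ACTA2 had 2 on chromosome 10, at 90711375 to 90711617 in intron 1 of 8 and at 90712421 to 90712764, 11 bp from the TSS. KLF11 had no region of all 5 libraries and 1 region found in 4, whose distance to the TSS was 194 bp. Less recurrent regions also lay near other TSS, the nearest being 1 bp away for PGR, 142 bp for ESR1 and 672 bp for BCL2. TNFSF11 (RANKL), MED12 and HMGA2 were the nearest gene of 0 peaks in libraries 2 and 4, the lists that carry gene names.

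Recurrence went far beyond what placement by chance gave. Of the 88311 regions, 41756 held a peak of 1 library, 16745 of 2, 12305 of 3, 10057 of 4 and 7448 of all 5. In 100 random placements of the peaks on their chromosomes, the highest number of regions with all 5 libraries was 0. In 100 placements that shifted each peak by 5 to 50 kb, chosen after seeing the data to keep the local density of peaks, it was 1. The share of a library's peaks in regions of all 5 was 11.8%, 63.4%, 19.2%, 23.7% and 16.8% in libraries 1 to 5, or 27.0% ± 20.8 (SD, n = 5). For the 10 pairs of libraries, a median of 76.6% of the shorter list's peaks overlapped the other list, from 60.6% for libraries 3 and 4 to 85.8% for libraries 2 and 5. The base-pair Jaccard index was 0.0567 to 0.306. Within regions of all 5, peak centres of a pair of libraries lay a median of 25 to 34 bp apart, and heights had Spearman correlations of 0.474 to 0.783 across regions, which are not independent replicates. Without library 2, 15432 regions held a peak of all 4 remaining libraries, and with lists cut to the 12015 highest peaks of each library 3656 held all 5.

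**Figure D2:**
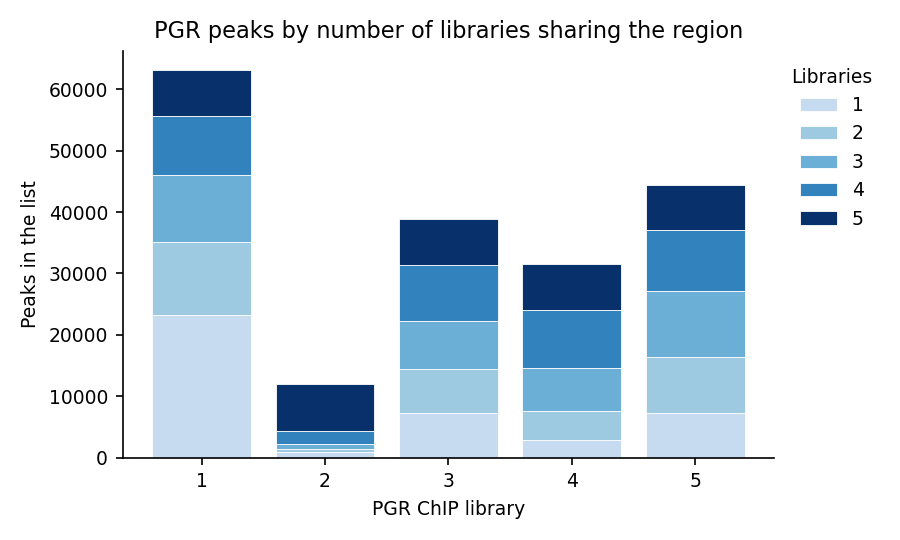
Stacked bars of the number of PGR peaks in each library's list, starting at 0, split by how many of the 5 libraries have a peak in the same region. Library 2 has the shortest list, 12015 peaks, and the greatest share in regions of all 5 libraries, 63.4%.

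Regions such as those at FKBP5, ZBTB16 and PER1 were high in every list. As a class, peaks in shared regions were higher than peaks found in 1 library, by only 1.27-fold in library 2. The median height in regions of all 5 libraries was 34.3, 5.51, 11.6, 14.6 and 17.7 in libraries 1 to 5, against 7.0, 4.35, 4.5, 5.46 and 5.26 for peaks found in that library alone. The log2 ratio was 1.43 ± 0.71 (SD, n = 5) and above 0 in 5 of 5 libraries, and the exact sign-flip permutation test gave a two-sided p of 0.063, the smallest that 5 libraries allow. Among peaks of the highest height decile, 57.5%, 92.2%, 70.6%, 80.7% and 72.4% lay in regions of all 5 in libraries 1 to 5, and among those of the lowest decile 0.626%, 42.4%, 1.83%, 1.49% and 0.338%. Enrichment over the chromatin input of the same tumour, the background of the assay, followed the same order. It is computed from the tags of the same peaks, so it is not independent of height. In libraries 1, 3 and 5 the median fold over input was 30.7, 18.8 and 22.0 in regions of all 5 and 8.52, 8.46 and 8.92 in single-library peaks. The log2 ratio was 1.43 ± 0.37 (SD, n = 3), with a two-sided exact sign-flip p of 0.25, the smallest that 3 libraries allow.

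**Figure D3:**
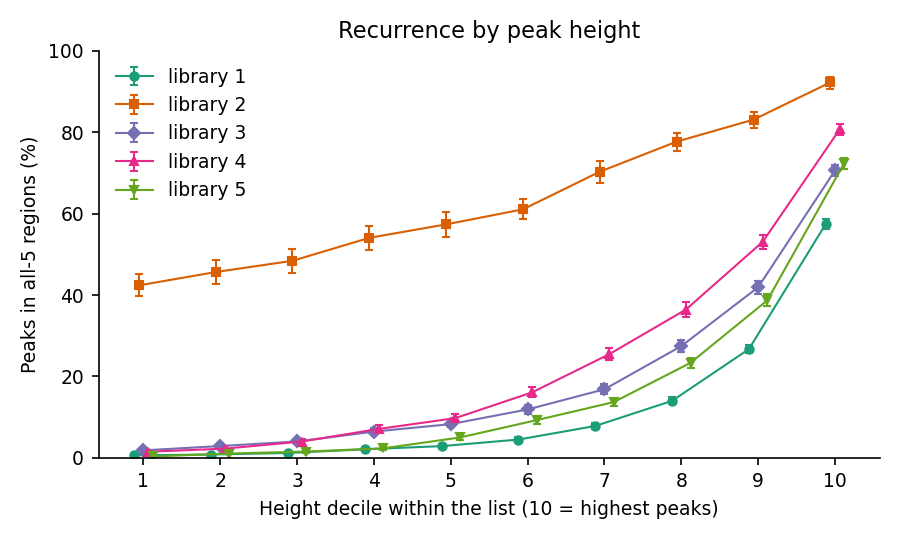
Share of peaks in regions of all 5 libraries, in percent, against the height decile of the peak within its own list, with 95% Wilson intervals, for each of the 5 libraries. In the highest decile the share runs from 57.5% in library 1 to 92.2% in library 2.

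The next question was which genes the shared regions lay near. Genes of the smooth muscle contractile apparatus, the circadian clock, the extracellular matrix, the immediate early response and the response to progesterone and glucocorticoids were the nearest gene of such a region 3 to 4 times as often as unmatched random genes. Of 19976 protein-coding genes, 3454 (17.3%) were the nearest gene of a region of all 5 libraries. Of the 21 gene lists, all fixed before the data were examined, 9 exceeded 10000 random lists of the same size at a Benjamini-Hochberg adjusted one-sided permutation p under 0.05. The random genes were not matched for gene length, so long genes and genes with wide intergenic surroundings count in a list's favour.

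Smooth muscle contractile genes had the greatest share, 21 of 28 against 4.85 expected (4.33-fold, adjusted permutation p = 0.000525, 1e-04 being the smallest unadjusted p the random lists can give). The intermediate filament gene DES was bound 124 bp from its TSS on chromosome 2 at 220282890 to 220283123, with a mean height percentile of 97.1 ± 1.00 (SD, n = 5). CSRP1, a LIM protein of smooth muscle, was bound in intron 2 of 5 on chromosome 1 at 201465068 to 201465296, at 97.9 ± 1.53 (SD, n = 5), and CALD1 (caldesmon) 143 bp from its TSS on chromosome 7 at 134463911 to 134464182. Clock genes followed with 11 of 16 (3.96-fold, adjusted permutation p = 0.000525). Besides PER1, they included the leucine zipper factors HLF and TEF, with mean percentiles of 95.5 ± 4.11 and 91.2 ± 3.61 (SD, n = 5), and the nuclear receptor NR1D1, bound 1.40 kb from its TSS on chromosome 17 at 38255436 to 38255668. The extracellular matrix list had 26 of 42 (3.58-fold, adjusted permutation p = 0.000525), among them the microfibril gene MFAP5, bound 1.93 kb upstream on chromosome 12 at 8817300 to 8817527 with a mean percentile of 99.4 ± 0.461 (SD, n = 5), THBS2, COL18A1 and SPARC.

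AP-1 and immediate early genes had 12 of 20 members (3.48-fold, adjusted permutation p = 0.000700). NR4A1, an orphan nuclear receptor, was bound in intron 2 of 7 on chromosome 12 at 52438193 to 52438409, IER3 7.87 kb upstream on chromosome 6, the mRNA decay factor ZFP36 2.92 kb upstream on chromosome 19 and FOS 1.67 kb upstream on chromosome 14 at 75743693 to 75743909. Progesterone and glucocorticoid response genes had 19 of 36 (3.06-fold, adjusted permutation p = 0.000525), of which ZBTB16 had the highest-ranked region, and NFKBIA, FKBP5, PER1 and CRISPLD2 the highest within 20 kb of the TSS, CRISPLD2 being bound in intron 1 of 14 on chromosome 16 at 84866214 to 84866430 with 50.2 to 113 times the input. These 5 lists passed in each of the 13 other settings tried, with smaller ratios in some. A comparison chosen after seeing the data used random genes of the same class of number of less recurrent regions. It had 6 classes, the highest without an upper limit. There the ratios were 1.81 for smooth muscle, 3.08 for the clock, 1.52 for matrix, 2.66 for AP-1 and 1.5 for progesterone and glucocorticoid response genes. The last had an adjusted permutation p of 0.0479. Against unmatched random genes, leaving out library 2 gave ratios of 2.65, 2.71, 2.43, 2.16 and 2.15 in the same order. With all 5 libraries the unmatched ratios were 4.33, 3.96, 3.58, 3.48 and 3.06.

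WNT signalling had 15 of 30 (2.89-fold, adjusted permutation p = 0.000700), with CTNNB1 (beta-catenin) bound 29 bp from its TSS on chromosome 3 at 41240774 to 41240990, RSPO3 in intron 1 of 4 on chromosome 6 at 127450038 to 127450347, DKK3 and FZD7. Genes altered in leiomyoma had 6 of 13 (2.69-fold, adjusted permutation p = 0.0334), of which HMGA1 alone had a region within 20 kb, 12.7 kb upstream on chromosome 6. Nuclear receptors and cofactors had 12 of 29 (2.42-fold, adjusted permutation p = 0.00604), including RXRA in intron 1 of 9 on chromosome 9 and RARA 39 bp from the TSS. TGF-beta family signalling had 13 of 32 (2.36-fold, adjusted permutation p = 0.00450), including SKI, SMAD3 and SMAD6. These 4 lists did not pass the test when a region had to lie within 20 kb of the TSS, where the adjusted p was 0.114 for WNT, 1 for leiomyoma, 0.208 for nuclear receptors and 0.276 for TGF-beta. None of them passed against random genes of the same class of number of less recurrent regions. There the ratios were 1.48 for WNT, 1.40 for leiomyoma, 1.19 for nuclear receptors and 1.12 for TGF-beta (adjusted permutation p 0.0955, 0.356, 0.474 and 0.652). Of the 13 other settings, WNT and nuclear receptor genes passed in 10 each, TGF-beta genes in 8 and genes altered in leiomyoma in 6. The calls for TGF-beta and leiomyoma genes were lost with the upper 50% of each list (adjusted permutation p 0.0807 and 0.256) and with equal lists (0.255 and 0.0633). That for leiomyoma genes was lost with at least 3 libraries (0.192) and within 100 kb (0.253) as well.

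The remaining 12 lists did not pass, and adjusted permutation p-values stand in brackets. Cell cycle genes had 8 of 24 (adjusted permutation p = 0.0830), with the CDK inhibitor CDKN1C at a mean percentile of 99.6 ± 0.253 (SD, n = 5) and CCND3 at 98.0 ± 0.888 (SD, n = 5). Growth factor and PI3K signalling had 11 of 36 (adjusted permutation p = 0.0752; IGFBP4, FGF2, HBEGF and EGFR within 20 kb), the stem cell and RANKL axis 5 of 15 (0.163; NT5E, ABCG2 and KLF4) and the tryptophan and aryl hydrocarbon receptor pathway 3 of 15 (0.690; TDO2, TIPARP and HAAO). DNA methylation enzymes had 2 of 12 (0.842; TET3) and apoptosis regulators 3 of 22 (0.924). Markers of other cell types the tissue could hold had 5 of 14 for endothelium (0.138), 0 of 20 for immune cells (1) and 1 of 16 for epithelium (1). Neuronal genes had 2 of 16 (0.924), liver genes 2 of 18 (0.937) and housekeeping genes 6 of 24 (0.332; EEF1A1, RAB7A and TUBB). Without library 2, growth factor genes (adjusted permutation p = 0.000350), cell cycle genes (0.00289) and housekeeping genes (0.0416) passed. Of the 13 other settings, growth factor genes passed in 7, cell cycle genes in 3, and housekeeping genes and DNA methylation enzymes in 1 each. Among these were growth factor genes without library 1, 3 or 4 (0.0309, 0.0460 and 0.0468), and cell cycle genes without library 4 (0.0468). With every peak of a single list, 10 gene lists passed in library 2 and 9 in library 4. There, smooth muscle genes had 24 and 27 of 28, and immune markers 0 of 20 in both.

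**Figure D4:**
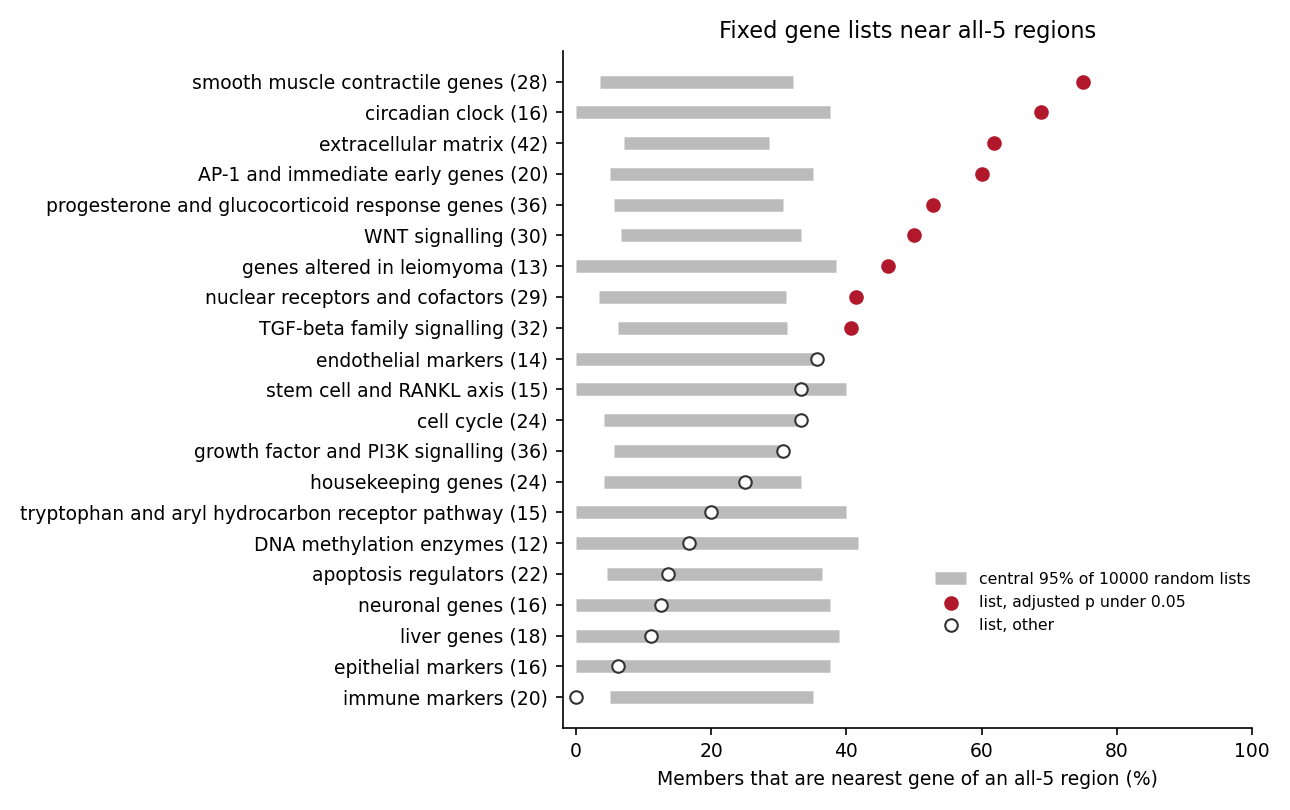
Share of each fixed gene list's members, in percent, that are the nearest gene of a region of all 5 libraries, with the number of members in brackets; grey bars hold the central 95% of 10000 random lists, filled points have an adjusted p under 0.05. Smooth muscle contractile genes stand at 21 of 28 and immune markers at 0 of 20.

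The last question was where the shared regions lay relative to genes. Promoters such as those of DES, CTNNB1 and CALD1 held 17.5% of the regions of all 5 libraries (1305 of 7448, Wilson 95% interval 16.7% to 18.4%), while introns held 41.1% and intergenic sequence 37.5%. The nearest TSS lay a median of 27342 bp away, within 20 kb for 43.9% of regions and beyond 100 kb for 19.8%. In library 2, 17.5% of peaks in regions of all 5 were at promoters against 8.57% of single-library peaks, and in library 4 17.5% against 295 of 2961. Peaks in regions of 4 libraries were at promoters in 16.4% in library 2 and 24.5% in library 4, and all peaks in 15.8% and 17.0%, so in library 4 the share was not highest in regions of all 5. Only these lists carry annotation, so the difference was not tested over libraries. Peaks of the promoter class were rare among the highest peaks, which included those at FKBP5, ZBTB16 and LAMA3. They made up 7.51% of the highest decile in library 2 and 5.16% in library 4, against 20.5% and 22.5% of decile 5. The strongest FKBP5 region, 439 bp downstream of the TSS, counts as intron in this class. The promoter share of shared regions was 12% with lists of equal length and 22.6% without library 2.

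**Figure D5:**
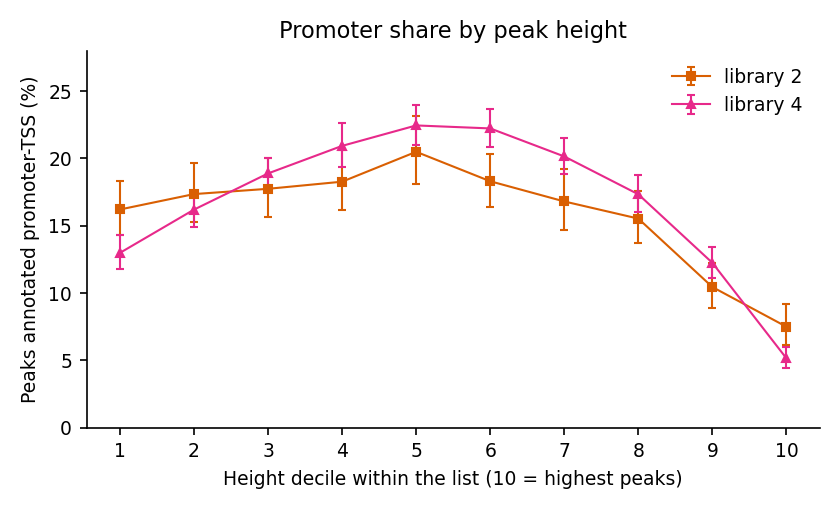
Share of peaks annotated to a promoter, in percent, against the height decile of the peak within its list, for libraries 2 and 4, with 95% Wilson intervals. The share falls to 7.51% and 5.16% in the highest decile.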

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

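The tests of depth and enrichment in library 2, of peak width and input background at promoters, and the division by library of the test of list length were chosen after their results had been seen. Library 2 stood apart from the other 4 in the share of its peaks in regions of all 5 libraries, 63.4%. It was also the lowest in 15 of the 20 named regions where a library's height percentile lay far from the rest. Those were 99.8 near NNMT, 99.9 near ZBTB16, 99.8 near ADARB1, 99.6 near LOC101928617, 99.3 near PIK3C2G, 96.5 near CCND3, 89.9 and 15.5 at the upstream regions of PGR, 70.3 near EEF1A1, 56.9 near CDKN1B, 50.7 near IGFBP4, 43.3 near RARA, 34.5 near HMGA1, 25 near SPARC and 15.5 near ABCG2. Library 1 was the lowest near NFKBIA (99.7), FKBP5 (99.6), TPRG1-AS1 (99.5) and DKK3 (51.8), and library 5 near HIF3A (99.5). In all, 85 sets of 5 values were tested, and chance flags about 1 in 20 of them if values are normally distributed. Percentiles cannot exceed 100, so that rate need not hold here. Regions of all 5 made up 63.4% of the peaks of library 2, against 11.8% to 23.7% in the other libraries. Lower percentiles of such regions in library 2 thus follow in part from the make-up of its list. Percentiles come from lists of different length, so a low percentile in the shortest list still marks a peak that was called.

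The shortest list set the size of the shared set, since 79.5% of the 10057 regions of 4 libraries lacked only library 2. Its depth argues against fewer tags as the cause, because the recovered depth was 105% of the lowest depth of the other libraries. This holds only if the true spacing of its heights lay in the range searched, which left out far lower depths. Overlaps missed through narrow peaks are argued against as well, because widening them to the 216 bp of library 1 gave 7572 regions, 1.02 times as many. Widening cannot add peaks that were never called, so whether narrow peaks shortened the list itself stays open. Weaker enrichment stays open: at least 95.2% of the 1000 highest peaks of library 2 were found in each other list, but its low share of tags in peaks, 0.713%, follows in part from its few and narrow peaks and decides nothing. A difference in peak calling stays open too, because the call settings of library 2 are not given. Its lowest peak height came to 9 tags by the spacing of heights, against 11 in libraries 4 and 5. The labels give no group that separates library 2, so no biological explanation was tested.

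Promoter peaks of libraries 2 and 4 were found in libraries 1 and 3 more often than other peaks of the same height, and averaged over height deciles the gap was 14.8 and 25.5 percentage points for peaks of library 4, and 12.4 and 14.7 for peaks of library 2, while for library 5 it was 0.749 and 4.56. For library 3, peak width is argued against, because libraries 3 and 5 have nearly equal widths and their gaps differed by a mean of 17.4 points. That comparison says nothing of library 1, whose peaks are the widest at 216 bp, so peak width stays open there. Raised input background at promoters is argued against as the whole cause, because over all annotated regions with a peak of the library, less recurrent ones included, the ratio of median input tags at promoters to those elsewhere was 1 in libraries 1 and 3 (ratios of means 0.993 and 0.993). Input tags are listed only at called peaks, and there the median fold over input was 16.2 at promoters against 19.8 elsewhere in library 1, 11.5 against 14.1 in library 3 and 10.4 against 15.7 in library 5, with median heights also lower at promoters in these 3 libraries. List length stays open, since with lists of equal length the gaps for peaks of libraries 2 and 4 were -2.33 and 8.71 in library 1 (mean 3.19), 5.12 and 20.8 in library 3 (mean 13, and 8.08 over both libraries) and -19.7 and -9.90 in library 5, and no biological explanation was tested.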

How the results depend on the processing

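No paired analysis was possible because the input libraries have no table of their own here, so ChIP and input were not fitted as samples with the replicate number as a block; the sign-flip tests and fold over input compare values within a library. Motif shares, with windows of 50 bp and flanks at 5 kb among their alternatives, were not run. The distance of 20 kb, the matching on less recurrent regions, the shifted placements, and the other settings for pairs of libraries and for fold over input were chosen after seeing the data. The log2 ratios of height and of fold over input kept their direction in all settings, and no setting could bring them past the threshold. With the upper 50% of each list, 4035 regions had all 5 libraries and 14.5% of them were at promoters. With equal lists these were 3656 and 12%, and the median overlap of pairs was 55.6%. Regions of at least 3 libraries numbered 29810 and held 66.7% of a library's peaks, and of the 24885 with annotation 19.5% were at promoters. With 1 kb on both sides of the TSS the promoter share was 19.3%. Leaving out a library gave 7558 to 15432 regions and a promoter share of 16.4% to 22.6%, the upper values without library 2. The cause of these shifts was not tested, beyond fewer or more peaks entering. Of the gene lists, 5 passed at 5 kb, at 20 kb and with matched genes, in place of 9. Over all lists and settings whose ratio stayed on the same side of 1, 16 calls were lost, 11 were gained and 223 kept their side of the threshold. Ratios that crossed 1 were, at 5 kb, genes altered in leiomyoma and endothelial markers (both 0), the stem cell axis (0.850) and tryptophan (0.862), and at 20 kb leiomyoma (0.701) and endothelium (0). With matched genes they were growth factors (0.908) and tryptophan (0.911). With the upper 50% they were apoptosis (1.36) and the stem cell axis (0.658), and with equal lists apoptosis (1.53) and housekeeping (0.914). With at least 3 libraries they were apoptosis (1.33), DNA methylation (1.81) and neuronal genes (1.05), and DNA methylation also at 100 kb (1.07) and with 50% overlap (1.04). Over the 5 libraries left out in turn, ratios ranged from 0.787 to 1.13 for apoptosis (main 0.791), 0.894 to 1.54 for DNA methylation (0.959) and 0.686 to 1.00 for neuronal genes (0.725). Of these, DNA methylation passed the list test with at least 3 libraries, and the cause was not tested. Libraries with few tags in peaks limit what depth can show, so a region missing from library 2 is not shown to be unbound there.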

Other observations

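The genes of this paragraph were chosen after their values were seen. Some genes were the nearest gene of many regions of all 5 libraries. RAD51B, a recombination gene and a fusion partner in leiomyoma, was the nearest gene of 12 such regions on chromosome 14 between 68407684 and 68683192. The non-coding gene LOC100996664 was that of 16 more between 68699158 and 69106554. C10orf11, LINC00595 and LINC01287 had 11 each. The developmental regulator TBX3, the semaphorin co-receptor NRP2, and PALLD and SVIL, which encode proteins of the actin cytoskeleton, had 9 each. Those 9 were spread over 686, 620, 220 and 263 kb in the same order. ZBTB16 had 8, spread over 124 kb. The counts were not corrected for the length of a gene or its surroundings. In library 4, 13.6% of peaks in regions of all 5 overlapped an annotated repeat, against 22.2% of single-library peaks, and in library 2 these shares were 14.1% and 18.6%.

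The tests of this paragraph were all chosen after their results had been seen. Genes with wide surroundings collect more peaks, so the 9 gene lists that passed may owe this to gene territory. Each list was therefore set against random genes of the same class of number of annotated regions found in fewer than 5 libraries. There were 6 such classes, the highest without an upper limit. The matching uses peaks of the same libraries, and so can also remove real binding. Ratios of observed to expected members then stood at 3.08 for the circadian clock, 2.66 for AP-1 and immediate early genes and 1.81 for smooth muscle genes. They were 1.52 for extracellular matrix and 1.5 for progesterone and glucocorticoid response genes. Adjusted permutation p ran from 0.00105 to 0.0479 over these 5. This argues against territory as the whole cause for them, as far as the 6 classes capture it. Territory that differs within a class was not removed. Smooth muscle, matrix and progesterone and glucocorticoid response genes still fell nearer to 1 than to their unmatched ratios of 4.33, 3.58 and 3.06. Much of their excess thus went with the matching. Nuclear receptors (1.19), TGF-beta signalling (1.12) and genes altered in leiomyoma (1.40) also fell nearer to 1 than to their unmatched ratios and did not pass, so territory stays open for them. WNT signalling (1.48, adjusted permutation p = 0.0955) could be either. Housekeeping genes were near shared regions less often than smooth muscle genes (Fisher's exact test, two-sided p = 0.000674). That test was not matched for territory, so it cannot decide whether broad expression was the cause for smooth muscle genes. Against matched genes the ratio was 1.70 for housekeeping genes (6 members against 3.53 expected, adjusted permutation p = 0.329). For smooth muscle genes it was 1.81 (adjusted permutation p = 0.00140). The ratios are close and 6 members are few, so broad expression stays open.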
